A study of Drosophila melanogaster with 17 samples.

How the data were processed

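Small RNA of Drosophila melanogaster Schneider 2 cells was measured in 17 libraries. Per the labels, cells were grown in Schneider's medium with 10% FBS at 25 °C and incubated with 500 µM s4U for the stated time, and total RNA was alkylated with iodoacetamide. The treated RNA was split, and 1 portion was oxidised with NaIO4. RNA of 18 to 30 nt was selected, 2S rRNA was depleted, and both adapters carried 4 random nucleotides at the ligation interface. The groups were unoxidised (8 libraries, 0 to 24 h), oxidised (8 libraries, the same times) and 1 library without s4U and IAA. Libraries of the same time were treated as pairs because they come from the same RNA.

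Per the submitters' processing notes, the authors used cutadapt 1.7.1, Bowtie 1.2.2 and Picard on the dm6 build; the version of Picard and the settings are not given in the sources used here. The deposited mismatch tables hold counts: reads that show each nucleotide at each position of a miRNA arm. The deposited library tables hold counts of small RNA and miRNA reads. The deposited position and length tables hold a signal in RPM (reads scaled to the small RNA reads of the library), and 100% of their values multiplied by the library total were whole reads (tolerance 0.001). In the values themselves, the mismatch tables hold arms with a mean of at least 5.00 (unoxidised) or 5.24 (oxidised) RPM, 135 arms of 86 hairpins and 97 arms of 64 hairpins. The position tables hold 301 and 236 arms. Of the hairpins 94 of 96 were matched to the BDGP6 annotation by FlyBase identifier, which gave the coordinates (1-based) and host genes.

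Depth in miRNA reads was 10321559 to 13199979 in the unoxidised time course and 1386443 to 5610093 in the oxidised one. Shares of reads carry exact Clopper-Pearson 95% intervals. The T>C percentage is T>C reads over all reads at U positions, summed over the arms with a mean of at least 100 RPM in the unoxidised group; tests of single arms also needed 1000 reads over U positions. Of arms that share their mature sequence 1 copy was kept and 9 arms were left out. Background is the 0 h library of the same group. The more abundant arm of a hairpin was taken as the guide.

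Abundance was tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) on the mismatch-table counts, with labelling time as a block for oxidation and a slope on log2(1 + h) for time, in R 4.3.3. Limma 3.58.1 gave camera (correlation 0.01, and estimated) and DESeq2 1.42.0 the second tool. Oxidation used 80 arms out of 84 with the same start in both groups. For a second count from the position tables, 17 unoxidised arms that the oxidised table does not list at the same start were left out; an earlier form of that count had wrongly taken them as 0 reads. Lists were tested against the other arms, and each was also adjusted over its own members. Permutation tests over arms or hairpins used 100000 resamples (seed 7), and tests over libraries were exact. P-values were adjusted with Benjamini-Hochberg at 0.05. Kinetics used a least squares rise to a plateau from 0 to 24 h. Other values came from Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

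The tests, lists, filters, the rule for named miRNAs and the first set of alternatives were fixed before the data were examined. The rule took the 10 highest and 10 lowest fold changes among arms past the threshold with at least 100 RPM in either group, the 10 most abundant guides, the 5 highest and 5 lowest 24 h T>C percentages of each group, the 5 hairpins with the largest difference each way, the 5 highest 3′ end values, and the measured members of the mirtron, Ago2-loaded, Nibbler-trimmed and other-cell-type lists. Other miRNAs that the text names were chosen after their values were seen, such as bantam-3p in the oxidation comparison, the examples at 0.5 h, the kinetics examples and miR-12-3p, miR-1002-5p, miR-996-3p and miR-276b-3p in the time test.

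The planned measure of tails could not be used as written, because the tables have no column for a tail. Bases from nucleotide 21 on that differ from the hairpin were counted instead, so a read that ends earlier cannot contribute. The length of T>C reads was compared with that of all reads of the arm in arms with at least 200 T>C reads. This measure was changed after its values were seen: the first form subtracted 1 T>C share of 0 h for all lengths and did not correct for the number of U, the second used the 0 h share of the same length, corrected for the number of U and asked for at least 100 T>C reads above that share, and the reported form asks for at least 50% of the T>C reads above it. Alternatives covered scaling, filters, background, tools, the block, the kinetic plateau, U positions to nucleotide 18, and leaving out libraries. The abundance tests, the kinetic fit and the length measure were tested on simulated data of the same depth: of log2 changes of 1 the oxidation test recovered 81.0%, with 3.98% of its calls false.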

Results

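The data set holds 17 small RNA libraries of Drosophila Schneider 2 (S2) cells, a macrophage-like embryonic line that carries an active miRNA pathway and RNA interference. Cells were fed 500 µM 4-thiouridine (s4U), a uridine analogue that enters RNA as it is transcribed, for 0, 0.25, 0.5, 1, 3, 6, 12 or 24 h. Iodoacetamide (IAA) then alkylated the incorporated s4U, so that reverse transcription reads it as C and a labelled molecule shows a T>C mismatch. Each treated RNA was split. One portion was sequenced directly (unoxidised, 8 libraries) and the other after NaIO4 oxidation (oxidised, 8 libraries), which keeps small RNAs out of the library unless their 3′ end carries a 2′-O-methyl group. Small RNAs loaded into Argonaute2 (Ago2) receive this group, whereas most miRNA guide strands sit in Argonaute1 (Ago1) without it. A further unoxidised library had neither s4U nor IAA. The unoxidised libraries, this one included, held 19041816 to 28351872 small RNA reads and the oxidised ones 19074278 to 42511487. Reads on miRNAs made up 54.3% ± 1.49 (SD, n = 8) of the small RNA reads in the unoxidised group and 9.53% ± 1.89 (SD, n = 8) in the oxidised group. The 8 libraries of a group are 8 labelling times and not replicates of a time. P-values of tests over libraries therefore measure the spread between these libraries. Those of camera and of permutations over arms or hairpins measure the spread between arms or hairpins. Fisher's exact tests, intervals and floors of counts cover counting error only. Where they span several U positions, each U of a read is counted apart. They then treat the U of 1 molecule as independent and may be too narrow even for counting error.

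The first question was how fast new miRNA molecules appeared. T>C mismatches rose at every step of the unoxidised series, from 0.0531% of the reads over U positions at 0 h to 0.104% at 0.25 h, 0.221% at 1 h, 0.457% at 3 h, 0.680% at 6 h, 1.42% at 12 h and 2.06% at 24 h, summed over 72 miRNA arms. In the oxidised series the percentage was 0.0481% at 0 h and 0.0369% at 0.25 h, and then rose to 0.0917% at 1 h, 0.192% at 3 h, 0.317% at 6 h, 0.549% at 12 h and 1.05% at 24 h, summed over 67 arms. The exact (Clopper-Pearson) 95% interval at 24 h ran from 2.06% to 2.06% in the unoxidised library and from 1.05% to 1.06% in the oxidised one. The library without s4U and IAA lay at 0.0445%. The percentage followed time in both groups (unoxidised Pearson r = 0.987, exact permutation p = 2.48e-05, and Spearman rho = 1.00, exact p = 4.96e-05; oxidised r = 0.999, exact p = 7.44e-05, and rho = 0.976, exact p = 0.000397; 4 relations, largest adjusted p 0.000397). Without the 2 libraries farthest from the median time, r was 0.988 and 0.996. No other mismatch type at 24 h exceeded 0.203% in the unoxidised or 0.133% in the oxidised library.

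**Figure D1:**
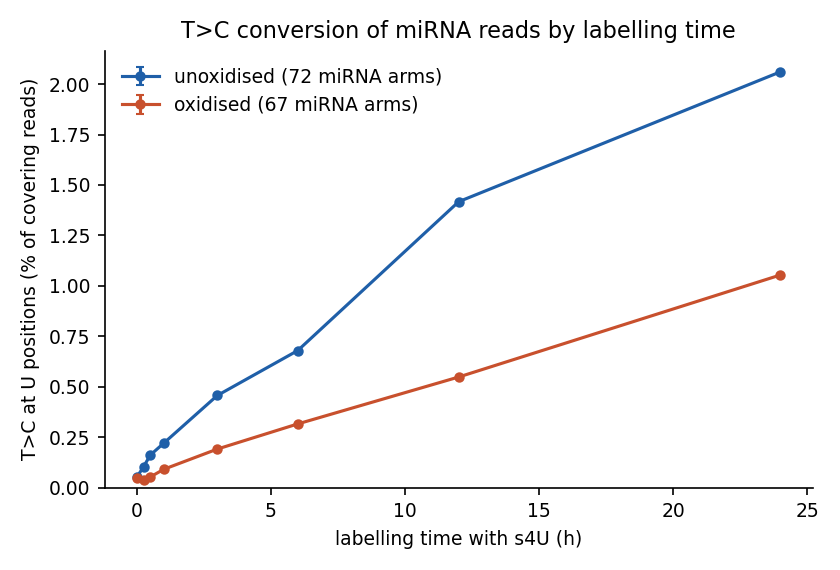
T>C mismatches in percent of the reads over U positions (vertical axis) against labelling time in hours (horizontal axis), 1 point per library, for the unoxidised and the oxidised libraries. The unoxidised series reaches 2.06% and the oxidised series 1.05% at 24 h.

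Nearly all abundant miRNAs carried label by 0.25 h in the unoxidised libraries. Against the 0 h library, 65 of 72 arms carried more T>C at 0.25 h, 71 at 1 h and all 72 from 3 h on (one-sided Fisher's exact test per arm, Benjamini-Hochberg adjustment, a comparison of 2 libraries). In the oxidised libraries 5 of 65 arms passed at 0.25 h, 46 of 67 at 1 h and 63 of 66 at 24 h. The 1 h count was not adjusted for long reads with high T>C in some arms of that library, described below. Bantam-3p, which represses apoptosis genes, was the most abundant guide strand, with 147021 ± 16133 RPM (reads scaled to the small RNA reads of the library; SD, n = 8). Its T>C percentage was 0.0333% at 0 h, 0.133% at 1 h and 1.74% at 24 h. Over the other 9 most abundant guides (miR-14-3p, miR-184-3p, miR-2a-1-3p, miR-2b-1-3p, miR-8-3p, miR-13b-2-3p, miR-11-3p, miR-276a-3p and miR-282-5p) the 24 h percentage lay between 1.95% for miR-2a-1-3p and 3.44% for miR-184-3p.

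Individual arms differed in their 24 h labelling by more than their counting intervals. In the unoxidised library miR-308-3p (chromosome 2R, 14215802 to 14215864, in an intron of RpS23) was highest at 5.37% (exact interval 5.31% to 5.43%), followed by miR-184-3p at 3.44%, miR-8-5p at 3.39%, miR-277-3p at 3.37% and miR-1012-3p at 3.22%. The value of miR-308-3p rests largely on nucleotide 3 of the arm, counted from its 5′ end, where 18.4% of the reads showed C. The lowest were miR-2c-3p at 0.501%, miR-281-2-5p at 0.882%, miR-986-5p at 0.95%, miR-33-3p at 1.19% and miR-1008-3p at 1.28%. MiR-2c-3p is uncertain, because 91.7% of its 24 h reads were 18 to 20 nt long, a length at which the same reads are counted for its paralog miR-2a-1-3p. In the oxidised library miR-8-5p was highest at 2.91%, followed by miR-275-3p at 2.14%, miR-2b-1-3p at 2.11%, miR-184-3p at 2.07% and miR-996-3p at 2.04%. The lowest there were miR-968-5p at 0.358%, miR-278-3p at 0.410%, miR-986-5p at 0.470%, miR-14-5p at 0.475% and miR-79-3p at 0.621%.

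A miRNA duplex yields a guide strand, which stays in Argonaute, and a passenger strand, most copies of which are discarded. Passenger strands carried far more label at early times. At 0.25 h the median 0 h-subtracted T>C percentage was 0.405% over passengers and 0.0317% over guides of the same 27 hairpins, and the passenger was higher in 25 of 27. The median difference was 0.345 percentage points at 0.25 h (adjusted p = 0.0004, permutation test over hairpins), 0.734 at 1 h (26 of 27 hairpins, adjusted p = 0.0004), 0.505 at 3 h (24 hairpins, adjusted p = 0.002) and 0.365 at 6 h (20 hairpins, adjusted p = 0.006). At 12 h and 24 h it was 0.192 and −0.0297 points, which did not pass (adjusted p = 0.2 and 0.8). At 0.5 h miR-275-5p stood at 2.67% against 0.114% for its guide and miR-14-5p at 2.66% against 0.0680%. At 24 h the guide exceeded the passenger most in miR-308 (passenger minus guide −3.85 points), miR-9c (−1.25), miR-184 (−1.23), miR-277 (−1.13) and miR-998 (−0.707). The passenger exceeded the guide most in miR-8 (1.37), miR-11 (0.692), miR-995 (0.620), miR-282 (0.336) and miR-275 (0.334). The values of miR-308 and miR-8 rest in part on 1 position, nucleotide 3 of miR-308-3p (18.4% T>C at 24 h) and of miR-8-5p (6.14%). Hairpins are not independent replicates of the experiment.

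**Figure D2:**
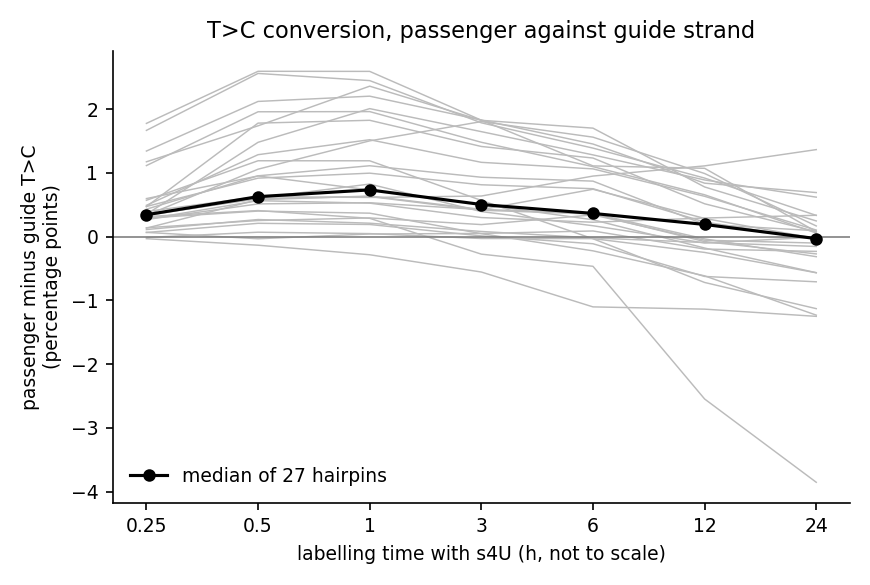
Passenger minus guide T>C in percentage points (vertical axis) by labelling time in hours (horizontal axis, not to scale), unoxidised libraries, 1 grey line per hairpin and the median of 27 hairpins in black. The median is 0.734 points at 1 h and −0.0297 points at 24 h.

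Mirtrons are short introns that are released by splicing, without cleavage by Drosha. The guides of 4 mirtrons passed the abundance filter: miR-1003-3p (intron of CG6695), miR-1006-3p (VhaSFD), miR-1008-3p (CG18004) and miR-1012-3p (Lerp). Their median 0 h-subtracted T>C percentage was 0.108% at 1 h against 0.160% for the 41 other guides, 0.304% against 0.425% at 3 h, and 1.64% against 2.07% at 24 h. No time passed an exact permutation test over the 148995 splits of the 45 guides (adjusted p 0.470 to 0.550 over the 7 times). At 0.25 h the difference was −0.00960 points, and 0.0169 points with a filter of 10 RPM, which also took the difference from −0.176 to −0.420 points at 12 h and from −0.431 to −0.715 points at 24 h.

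A rise to a plateau was fitted to each arm, and its time to 50% of the plateau is given here with the range of fits within about 2 standard errors. In the unoxidised libraries all 27 passengers had a fitted time within 24 h (median 0.646 h), as did 41 of 45 guides (median 13.5 h). The fitted plateau of these guides had a median of 142.6% of the 24 h value, and all 41 still rose from 12 h to 24 h. The guide times are thus times to 50% of a level that most guides had not reached at 24 h. A single rise did not describe the passengers: their median 3 h value was 48.9% of the 24 h value where the fits gave 96.0%, 24 of 27 still rose from 12 h to 24 h, and in 18 the 24 h value lay above the fitted plateau. The passenger median rose from 0.962% at 1 h to 1.03% at 3 h, 1.398% at 6 h and 2.04% at 24 h, so their fitted times describe an early rise and not the time to 50% of the level reached at 24 h. MiR-14-5p had 0.0893 h (0.05 to 0.1999 h, below the first labelled time of 0.25 h), bantam-5p 0.405 h (0.0820 to 2.44 h, with a plateau at 69.5% of its 24 h value and a 3 h value at 48.6%) and miR-34-3p 0.646 h (0.519 to 0.810 h). Bantam-3p had 21.2 h (12.2 to 66.3 h), miR-14-3p 19.4 h (13.2 to 34.6 h), miR-184-3p 11.6 h (10.2 to 13.3 h) and miR-277-3p, a regulator of branched-chain amino acid breakdown, 6.998 h (5.99 to 8.23 h). Of the mirtrons, miR-1012-3p had 4.09 h (3.22 to 5.24 h) and the other 3 lay between 13.5 h and 15.3 h. Independent of the fit, this 3 h share was 48.9% in the median passenger and 20.03% in the median guide (permutation p = 1e-05, the smallest that 100000 resamples can give). In the oxidised libraries the corresponding shares were 17.2% and 15.6% (permutation p = 0.3), and 9 of 42 guides and 5 of 24 passengers had a fitted time within 24 h. These counts rest on single libraries: without the 24 h library there were 22 unoxidised guides, 20 oxidised guides and 20 oxidised passengers, without the 12 h library 15 oxidised guides and 10 oxidised passengers, without the 6 h library 4 oxidised guides, and without the 3 h library 3 oxidised passengers. With 1 plateau for all arms, 21 oxidised guides and 9 oxidised passengers were within 24 h.

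Oxidation asks which strands carry the 2′-O-methyl group. Relative to the average miRNA arm guide strands fell and passenger strands rose (camera against the other arms, adjusted p = 1.14e-05 for each, and 0.00659 for guides and 0.0188 for passengers with an estimated correlation). Since every arm is a guide or a passenger, these are 1 comparison seen from both sides. On the scale of all small RNA reads, where camera was not run, the passenger median turned to −0.51. Of 80 arms measured in both groups, 35 were higher and 34 lower after oxidation (edgeR quasi-likelihood test, labelling time as a block, adjusted p under 0.05). Of the 48 guides 12 were higher, 30 lower and 6 not past the threshold, with a median log2 fold change of −1.49, and of the 32 passengers 23 were higher, 4 lower and 5 not past it, with a median of 1.695. Scaled instead to all small RNA reads, most of which are not miRNAs in the oxidised libraries, the median arm moved from −0.11 to −2.35, 8 arms were higher and 55 lower, the guides stood at 2 higher and 40 lower, and the passengers at 6 higher and 15 lower. With the library size of the miRNA counts alone, the median arm was 0.39. Fold changes below are relative to the average arm. Whole reads from the position tables, over the 109 arms listed at the same start in both groups, yielded 45 higher and 51 lower.

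Among the 80 arms, which had to pass the abundance limit of both mismatch tables and so leave out strongly depleted ones, the largest relative falls were in miR-306-5p (−6.47 ± 0.21 (SE), adjusted p = 2.71e-09, chromosome 2L, 16698404 to 16698488, intron of grp), miR-308-3p (−5.81 ± 0.42), miR-282-5p (−5.60 ± 0.32), miR-14-3p (−4.85 ± 0.45, a suppressor of cell death, chromosome 2R, 9553762 to 9553824), miR-317-3p (−4.58 ± 0.15), miR-965-3p (−4.42 ± 0.38), miR-34-3p (−4.12 ± 0.49), miR-980-3p (−3.90 ± 0.25), miR-2b-1-3p (−3.81 ± 0.16) and miR-275-3p (−3.63 ± 0.23), each lower in 8 of 8 pairs. In the position tables the mirtron miR-1008-3p stood at −5.86 ± 0.17 beside −5.88 ± 0.22 for miR-306-5p. The largest relative gains were in miR-966-5p (4.13 ± 0.48, adjusted p = 1.30e-05, chromosome 2L, 6045627 to 6045713, intron of Pfas), miR-998-5p (3.86 ± 0.25, intron of E2f1), miR-988-5p (3.67 ± 0.38), miR-2a-2-5p (3.33 ± 0.31), miR-306-3p (3.12 ± 0.21), bantam-5p (3.11 ± 0.23), miR-276a-5p (2.90 ± 0.10), miR-2279-5p (2.83 ± 0.15), miR-33-3p (2.81 ± 0.27) and miR-252-5p (2.67 ± 0.22), each higher in 8 of 8 pairs. Of 28 hairpins with a guide and a passenger among the 80 arms, the guide was lower and the passenger higher in 17, and in 5 on the small RNA scale. In the most abundant of them bantam-3p went from 147021 ± 16133 to 2866 ± 817 RPM (log2 −3.48 ± 0.17, adjusted p = 1.92e-08; chromosome 3L, 642208 to 642288, in a noncoding RNA exon) and bantam-5p from 5774 ± 811 to 11233 ± 4591 RPM (SD, n = 8 in each group), where bantam-5p was also higher on the small RNA scale (log2 0.87, adjusted p = 0.000558). The oxidised 0 h library stood apart from the other 7 for 6 of these 10 gains, above them for miR-966-5p (765 RPM), miR-988-5p (4587 RPM), miR-998-5p (2109 RPM) and miR-2a-2-5p (12916 RPM) and below them for miR-276a-5p (1287 RPM) and miR-2279-5p (33.2 RPM). Without the 0 h pair miR-966-5p was 3.62 ± 0.14 but had 76.8 RPM after oxidation, below the 100 RPM asked for, and miR-998-5p (3.50 ± 0.11) was the largest gain past that limit.

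**Figure D3:**
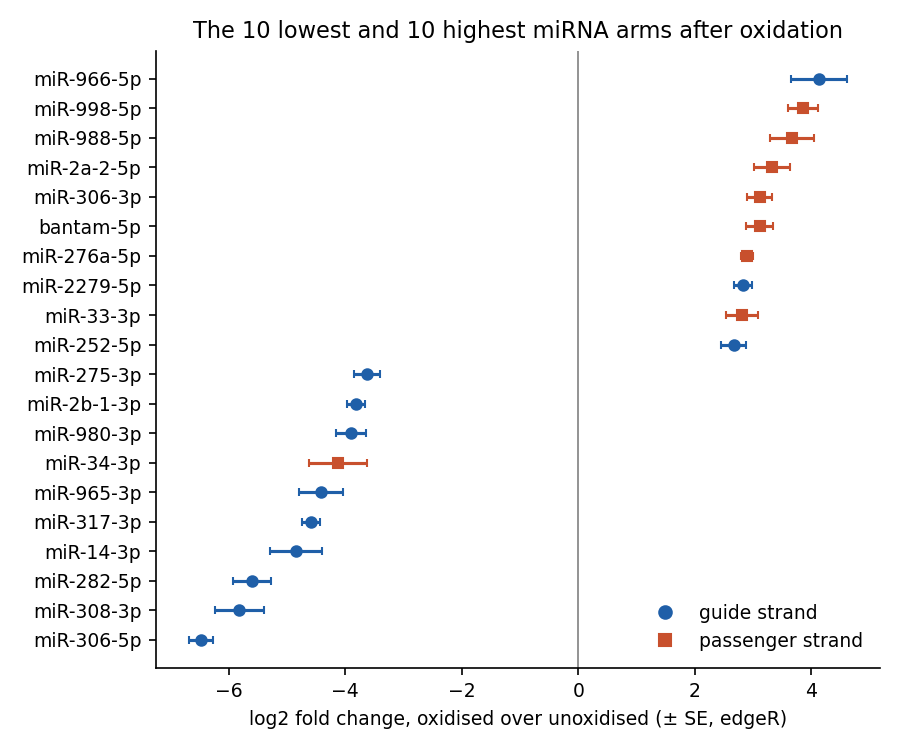
Log2 fold change of oxidised over unoxidised with its SE (horizontal axis) for the 10 lowest and the 10 highest miRNA arms (vertical axis), guides as circles and passengers as squares. The values run from −6.47 for miR-306-5p to 4.13 for miR-966-5p.

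Of the list of Ago2-loaded strands, made up of miR-277-3p and 12 passenger arms, 11 of 13 were higher and 1 lower, with a median of 2.10, and the counts adjusted over the list alone were also 11 and 1, whereas scaled to all small RNA reads 3 were higher and 4 lower, with a median of −0.15. Members included miR-14-5p (2.23 ± 0.29), miR-13b-2-5p (2.10 ± 0.13), miR-2b-2-5p (1.99 ± 0.28), miR-184-5p (1.46 ± 0.33), miR-8-5p (1.44 ± 0.14), miR-2b-1-5p (2.41 ± 0.16) and miR-277-3p (0.72 ± 0.17), miR-34-3p was the lower one, and miR-305-3p stood at −0.12 ± 0.13. On the small RNA scale miR-277-3p was −1.52 and miR-8-5p −0.81. The K-box family, which shares the miR-2 seed, had 5 of 6 members lower and 0 higher (median −3.30), also 5 when adjusted over the list alone, and miR-2c-3p did not pass (−0.30 ± 0.38). Of 21 guides chosen as abundant in S2 cells 16 were lower and 4 higher (miR-33-5p, miR-12-5p, miR-9c-5p and miR-252-5p), with a median of −2.27 and the same counts adjusted over the list alone. On the small RNA scale 19 of these were lower and 0 higher. Against the other arms, limma's camera called the Ago2-loaded list higher and the abundant guides lower (adjusted p = 0.00268 and 0.00268, and 0.0188 and 0.0188 with an estimated correlation) and the K-box family lower (adjusted p = 0.0177, but adjusted p = 0.248 with an estimated correlation). Since 12 of the 13 Ago2-loaded arms are passengers and the 21 abundant arms are guides, the first 2 calls largely repeat the comparison of guides with passengers. They are not separate evidence of loading into Ago2. Of the mirtron arms miR-1012-5p was higher (2.64 ± 0.16) and miR-1012-3p (−1.65 ± 0.19) and miR-1003-3p (−3.08 ± 0.45) lower, counts that did not differ when adjusted over the list alone (camera adjusted p = 0.801). Of the arms known to be trimmed by the exonuclease Nibbler, miR-263a-5p was higher (2.32 ± 0.23) and miR-34-5p lower (−1.97 ± 0.39), also when adjusted over the list alone (camera adjusted p = 0.801). No arm of the let-7 complex or of the markers of other cell types was among the 80.

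Label in the oxidised pool was compared with all miRNAs at matched times. After subtracting each group's 0 h library, the median arm carried a lower T>C percentage in the oxidised library at all 7 times. The median oxidised over unoxidised ratio was 0.102 at 0.25 h (37 arms with a ratio), 0.0716 at 0.5 h, 0.213 at 1 h, 0.319 at 3 h, 0.347 at 6 h, 0.338 at 12 h and 0.493 at 24 h (64 arms). The 1 h ratio was not adjusted for the long reads with high T>C in the oxidised 1 h library, described below. The mean of the 7 medians was −2.16 on the log2 scale (exact sign-flip permutation p = 0.0156, the smallest that 7 pairs can give). Without background subtraction it was −1.412. Over the 25 arms higher after oxidation it was −3.01 and over the 33 lower ones −1.21, a difference that was not tested itself. At 24 h 61 of 65 arms were lower, 1 was higher and 3 did not pass (Fisher's exact test, Benjamini-Hochberg adjustment). MiR-14-5p stood at 0.475% against 2.11%, miR-277-3p at 0.861% against 3.37%, miR-8-3p at 0.906% against 1.99% and bantam-5p at 0.704% against 1.48%, whereas bantam-3p stood at 1.36% against 1.74%. These ratios do not compare reads of 1 length. At 24 h bantam-3p held 25617 reads of 19 nt and 11660 of 23 nt oxidised, against 11292 and 2197156 unoxidised. MiR-14-3p held 8293 of 19 nt and 1676 of 22 nt oxidised, against 5381 and 1285891 unoxidised. In miR-305-5p, by contrast, 24 nt stayed the most frequent length (34761 and 109871 reads). These examples were chosen after their values were seen. The arm that was higher was miR-2c-3p, whose short reads are shared with miR-2a-1-3p. MiR-308-3p has no ratio because 4.90% of its U reads in the oxidised 0 h library already carried T>C. These medians leave out arms at or below background, 28 at 0.25 h. Over the same 64 arms at every time, with such arms kept, the medians were 0.0165 at 0.25 h, 0.0307 at 0.5 h, 0.182 at 1 h, 0.303 at 3 h, 0.329 at 6 h, 0.338 at 12 h and 0.493 at 24 h, with a rise in place of the fall from 0.25 h to 0.5 h. With the unoxidised 0 h library as background for both groups they were −0.0243 at 0.25 h, 0.0226 at 0.5 h and 0.484 at 24 h.

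The time test asked which miRNAs changed in relative level over the 24 h of labelling. In the unoxidised libraries 1 of 126 arms followed time, miR-980-3p, with a slope of 0.14 ± 0.02 (SE) log2 units per unit of log2(1 + h) (edgeR, adjusted p = 0.0206). The next by p-value were miR-12-3p at −0.14 ± 0.03, miR-1002-5p at −0.22 ± 0.05, miR-996-3p at 0.11 ± 0.03 and miR-277-3p at −0.13 ± 0.03, none past the threshold (adjusted p = 0.0585 for each). MiR-276b-3p, at 9.37 RPM, had a steeper slope of 0.27 ± 0.07 (adjusted p = 0.0585), which DESeq2 called at 0.28 (adjusted p = 0.00219). At an unadjusted p under 0.05 there were 32 arms, DESeq2 called 14, and a slope on hours 8. The count was 13 without the 6 h library, 8 without the 3 h library, 4 without the 0.25 h library, 15 without both the 3 h and 6 h libraries, and 0 without the 0 h, the 0.5 h or the 24 h library. In the oxidised libraries 0 of 93 arms passed with edgeR, 12 had an unadjusted p under 0.05, and DESeq2 called 1, miR-996-3p. In simulated data of these depths the oxidised test recovered 0.893% of slopes of 0.2. The unoxidised test recovered 87.5% of slopes of 0.2 and 12.1% of slopes of 0.1, so low counts do not show that levels stayed the same. Slopes differed between the groups in 0 of 80 arms (edgeR, interaction of oxidation with time), with 0 at an unadjusted p under 0.05, which does not show that they were the same.

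The 3′ ends differed between the pools. Over arms measured in both groups, the mean read length was 22.1 ± 0.0538 nt unoxidised and 21.6 ± 0.116 nt oxidised (SD, n = 8 each), a difference of −0.503 nt. Bases at the 3′ end that differ from the hairpin numbered 1.408 ± 0.0653 U per 100 reads unoxidised against 0.729 ± 0.0672 oxidised, and 1.21 ± 0.182 A against 0.369 ± 0.0413. Each of the 3 measures was lower in 8 of 8 oxidised libraries (exact sign-flip permutation p = 0.00781, adjusted p = 0.00781, the smallest that 8 pairs can give). The 3 measures are not independent: U and A were counted from nucleotide 21 on, which fewer of the shorter oxidised reads reach. These sums weight arms by their reads: without bantam-3p the differences were −0.233 nt, −1.21 U and −1.08 A, and for the median arm −0.300 nt, −0.427 U and −0.786 A. Reads of 21 nt made up 14.01% ± 0.994 of the unoxidised and 30.8% ± 1.89 of the oxidised reads, and reads of 23 nt 31.2% ± 1.24 and 18.5% ± 2.47. The highest 3′ U among arms past the filter was in miR-1008-3p at 36.7 ± 2.77 per 100 reads (SD, n = 8), followed by miR-1012-3p at 8.78 ± 1.05, miR-980-3p at 8.58 ± 0.498, miR-1003-3p at 6.82 ± 0.509 and miR-998-3p at 6.22 ± 0.433, 3 of which are mirtrons. After oxidation miR-980-3p fell to 0.660 ± 0.378, while miR-1003-3p and miR-1012-3p stood at 10.9 ± 1.99 and 10.9 ± 2.58. The 4 mirtron guides had a median of 7.80 against 1.34 for 41 other guides, a comparison prompted by these values and so not a test of them.

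**Figure D4:**
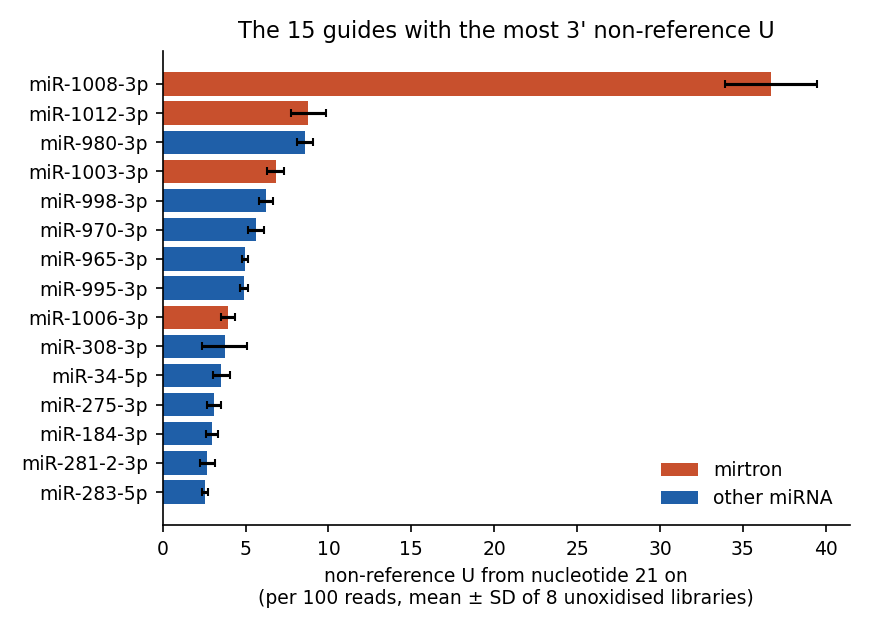
3′ U that differs from the hairpin, per 100 reads, as mean and SD of the 8 unoxidised libraries (horizontal axis), for the 15 guides with the most (vertical axis), mirtrons coloured apart. MiR-1008-3p stands at 36.7 and miR-980-3p, the highest other guide, at 8.58.

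Labelled reads of guides were longer than all reads of the same arm in the unoxidised libraries. The median excess, past what the larger number of U in longer reads gives, was 0.270 nt at 0.25 h (19 of 20 guides longer), 0.318 nt at 0.5 h, 0.304 nt at 1 h, 0.195 nt at 3 h, 0.133 nt at 6 h, 0.132 nt at 12 h and 0.0949 nt at 24 h (38 of 43 guides), with adjusted p between 5e-05 and 0.002 (permutation test over arms). MiR-34-5p, an arm trimmed by Nibbler, went from 1.64 nt at 0.25 h to 0.362 nt at 24 h. Passengers showed 0.203 nt at 0.5 h (20 of 21 arms, adjusted p = 0.002, permutation) and 0.0272 nt at 24 h (16 of 26 arms, adjusted p = 0.06). In the oxidised libraries labelled reads of guides were shorter at 24 h, by a median of −0.146 nt (4 of 25 guides longer, adjusted p = 0.003, permutation), and at 12 h, by −0.225 nt (1 of 17 longer, adjusted p = 0.006). The medians of −0.134 nt at 3 h and −0.110 nt at 6 h did not pass (adjusted p = 0.09 and 0.06), and that of −1.36 nt at 0.5 h was not tested (2 guides). At 1 h guides went both ways (median −0.0591 nt, 3 of 8 longer, not tested), among them bantam-3p, longer by 0.798 nt, with T>C in 2.61% of its 23 nt and 0.480% of its 18 nt reads. In miR-14-3p and miR-2a-1-3p, which the filter of the measure left out at 1 h, T>C was also more frequent in long reads (7.06% at 22 nt against 1.07% at 18 nt, and 1.97% at 24 nt against 0.643% at 18 nt), examples chosen after their values were seen. In these arms and bantam-3p, the long reads also exceeded those of the same length in the unoxidised 1 h and oxidised 3 h libraries. Bantam-3p stood there at 0.732% and 0.721%, and miR-2a-1-3p at 0.932% and 0.981%. MiR-305-5p and miR-34-5p at 24 nt were instead below the unoxidised 1 h library (0.620% against 2.89%, and 0.892% against 5.09%). The oxidised 1 h values may thus not reflect length alone, and the cause was not tested. In the same 25 guides the oxidised excess lay below the unoxidised one by −0.331 nt (lower in 23, permutation p = 0.0003). Read lengths differed between the pools in guides such as bantam-3p, as given above, so the 2 excesses are measured on unlike reads. The measure was revised after its values were seen. In the 20 guides measured at all 7 times the median excess was 0.270 nt at 0.25 h, 0.275 nt at 0.5 h and 0.143 nt at 24 h.

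**Figure D5:**
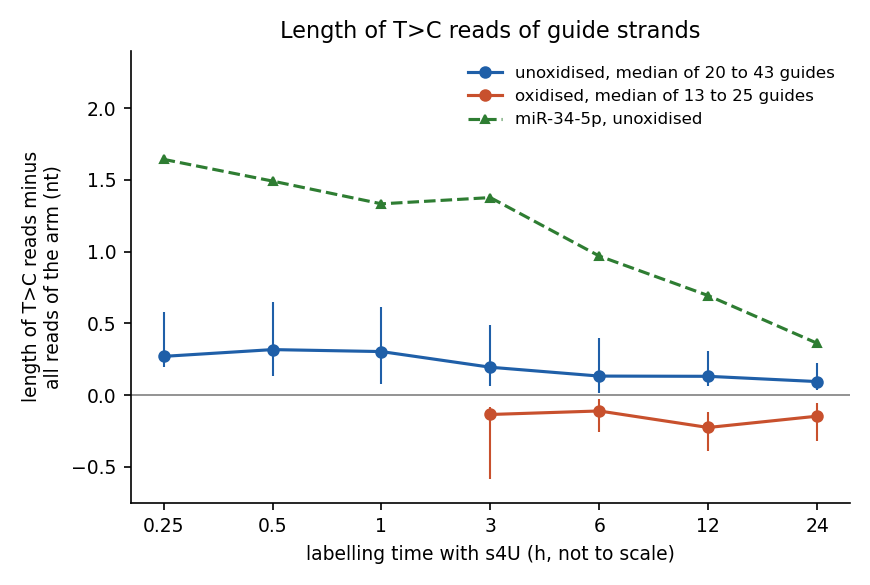
Mean length of T>C reads minus that of all reads of the same guide in nt (vertical axis) by labelling time in hours (horizontal axis, not to scale); points give the median of the unoxidised and the oxidised guides with their quartiles, and the dashed line miR-34-5p. The unoxidised median is 0.318 nt at 0.5 h and 0.0949 nt at 24 h, and the oxidised median −0.146 nt at 24 h.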

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

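The tests of explanations in this part and the comparison of labelled read lengths between groups were chosen after the results were seen. Of 96 groups of 8 libraries 20 held a library far from the others, against 4.8 by chance, which gives about 1 in 20 groups. The groups are not independent, since the same libraries recur.

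The unoxidised 6 h library was highest in A>C (0.0642%, next 0.0436%), A>G (0.143%, next 0.0751%), G>A (0.191%, next 0.137%), T>A (0.173%, next 0.141%), T>G (0.124%, next 0.0556%) and 3′ A (1.62 per 100 reads, next 1.205), and lowest in miR-8-5p (926 RPM, next 1231). The unoxidised 3 h library was highest in G>T (0.259%, next 0.187%) and the 12 h library in miR-34-5p (8981 RPM, next 7091). The oxidised 0 h library was highest in C>T (0.254%, next 0.161%), miR-966-5p (765 RPM, next 103), miR-998-5p (2109, next 1079), miR-988-5p (4587, next 1325), miR-2a-2-5p (12916, next 6805), miR-2b-2-5p (3177, next 1516), miR-263a-5p (197, next 123) and miR-34-5p (1707, next 484), and lowest in miR-276a-5p (1287, next 1908) and miR-2279-5p (33.2, next 109). The oxidised 1 h library was highest in miR-13b-2-5p (590 RPM, next 436). The groups differed in the length of labelled reads of 25 guides at 24 h (−0.331 nt).

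T>C in the oxidised 0 h library was high in miR-308-3p, at 4.90%, and at its nucleotide 3 at 12.5% (6 of 48 reads, exact interval 4.73% to 25.2%), against 0.173% in the unoxidised 0 h library. Reads from a labelled unoxidised library may contribute, but this arm prompted the question and cannot test it. In the 33 other arms lower after oxidation, the summed T>C percentage was 2.65 times that of the unoxidised 0 h library and the median arm 1.22 times, under the 1.5 set for this explanation, so it stays open. That limit takes no account of the other mismatch types given next, whose median fell in these arms. Some values argue against a general excess of mismatches. The median of the 11 other types in these arms was 0.464 times the unoxidised value (95% interval over resampled arms 0.346 to 0.551), 9 types lay below 1, with C>T highest at 1.86 times, and miR-308-3p itself held 14 T>C and 0 other mismatches. Fewer 3′ bases that differ from the hairpin may lower these ratios (at 0 h 0.297 A and 0.866 U per 100 oxidised reads, against 1.13 and 1.36 unoxidised). A general excess is therefore not excluded. No biological explanation was tested.

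Labelled guide reads were longer than all reads in the unoxidised libraries. The larger number of U in longer reads gave 8.80% of the shift at 0.5 h, under the 50% set for it as the cause. A loss of short labelled reads in mapping could also lengthen them in the oxidised libraries. There the median lay below 0 at all 6 measured times (past the threshold at 12 h, −0.225 nt, and 24 h, −0.146 nt), although 3 of 8 guides were longer at 1 h, where no test was run. Read lengths differed between the pools in guides such as bantam-3p, so the oxidised libraries are not a like control. Such a loss thus stays open for the unoxidised libraries. That molecules are made long and shortened later remains open as a hypothesis: in the 20 guides measured at all 7 times, Spearman rho with time was −0.679 (exact p = 0.110), which misses the condition of a p under 0.05 set for it. The outcome depends on a filter changed after the values were seen, since the earlier one gave 26 guides and rho −0.964 (exact p = 0.00278), and Pearson r with the reported filter was −0.899 (exact p = 0.0101).

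Labelled reads were fewer in the oxidised libraries at all 7 times. Loss of a fixed share by oxidation stays open as a part of the cause. Over the same 64 arms the 24 h median ratio was 2.71 times the 1 h and 1.63 times the 3 h one. With the lower of the oxidised 0 h and 0.25 h libraries as background these were 1.82 and 1.43 times. An excess past 1.5 times lay beyond the spread of the arms in 2 of 6 such comparisons. A fixed loss as the whole cause would give the same ratio at all times. With each group's 0 h library, the unoxidised 0 h library or that lower library as background, the 0.5 h medians were 0.0307, 0.0226 and 0.0907. At 24 h they were 0.493, 0.484 and 0.503. At 3 h, 6 h and 12 h they were 0.303, 0.329 and 0.338 with each group's 0 h library. They were level with the unoxidised 0 h library (0.351, 0.361 and 0.349) and with that lower library (0.353, 0.348 and 0.348). The case against a fixed loss as the whole cause thus rests mostly on early values, which lie near background, and on the 24 h pair. It does not exclude such a loss. Late entry of new molecules into the resistant pool may contribute, since the median ratio over these arms rose with time under each of 3 backgrounds (Spearman rho 1.00, 0.893 and 0.893; exact p = 0.000397, 0.0123 and 0.0123). This is a hypothesis found and tested on the same data. The 3 backgrounds reuse the same libraries, and the rise rests mostly on early ratios near background and on the 24 h pair. The 1 h ratios also include the long reads with high T>C described for the oxidised 1 h library.

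In 100 swaps of labels within pairs, the real one included, only the real one gave 69 arms past the threshold after oxidation (1 of 100). The highest other gave 56, with 1 pair swapped. Chance is thus unlikely, although 100 swaps cannot give less than 1 of 100. For the unoxidised time test 6 of 100 orders gave at least 1 arm and the highest other gave 11, so chance is not excluded. The oxidised count is 0, which 100 of 100 orders reach by necessity, so this comparison tests nothing. The highest other orders gave 11 arms in the unoxidised and 18 in the oxidised libraries, and what sets these orders apart was not tested. These tests over other splits were run after the counts were seen.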

How the results depend on the processing

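The alternatives that scale to all small RNA reads, use whole reads from the position table, or leave out chosen libraries were added after the data were seen. Of 848 alternatives over 217 results 734 kept their direction and their side of the threshold, 95 moved, 10 lost significance, 1 gained it and 8 reversed. For single miRNAs 519 of 600 were kept and for comparisons 215 of 248. Except where stated, the cause was not tested.

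Oxidation gave 35 arms higher and 34 lower. Scaled to all small RNA reads, which lowers the median arm from −0.11 to −2.35, it gave 8 and 55. Of the 35 higher arms 19 turned below 0 and 11 of these passed as lower; among those named in the report by rule, the reversed fold changes were those of miR-13b-2-5p (−0.15), miR-14-5p (−0.00078), miR-184-5p (−0.73), miR-277-3p (−1.52), miR-2b-2-5p (−0.24) and miR-8-5p (−0.81). Whole reads from the position tables gave 45 higher and 51 lower of 109 arms, and library size alone put miR-305-3p at 0.38. Without the time block there were 36 higher and 33 lower. With the block, the K-box call was lost with an estimated correlation (adjusted p = 0.248). Leaving out 1 pair gave 33 to 36 higher and 33 to 37 lower.

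The unoxidised time count of 1 became 14 with DESeq2, 8 with a slope on hours, 15 without the 3 h and 6 h libraries, and 0 to 13 when 1 library was left out; the oxidised count of 0 became 1 with DESeq2. The 24 h T>C percentage was 2.10% as the median arm, 2.14% within nucleotides 1 to 18 and 2.19% without the most abundant miRNA in the unoxidised library, and 1.15%, 1.14% and 1.13% in the oxidised one. The oxidised over unoxidised log2 ratio was −2.27 without the 1 h and 6 h pairs, too few pairs for an exact p under 0.05. The mirtron difference at 0.25 h reversed to 0.0169 points at 10 RPM.

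Fitted times within 24 h numbered 22 to 43 unoxidised guides, 4 to 20 oxidised guides and 3 to 20 oxidised passengers when 1 time was left out, and 21 oxidised guides and 9 oxidised passengers with 1 plateau for all arms. Without the 0, 1 and 6 h pairs the oxidised minus unoxidised differences at the ends were −0.549 nt, −0.711 U and −0.764 A per 100 reads, where 5 pairs cannot reach a p under 0.05. Tail shares from a tail column were not run. On simulated data with the depth and spread of these libraries the oxidised time test recovered 0.893% of slopes of 0.2, and depth was not tested apart from spread.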

Other observations

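The positions described here were chosen after their values were seen. Single positions carried T>C far from the rest of their arm. In miR-308-3p nucleotide 3 went from 0.173% at 0 h to 18.4% at 24 h in the unoxidised libraries, against a median position of 3.02% at 24 h. In miR-8-5p, the passenger of a miRNA that acts in insulin signalling of the fat body, nucleotide 3 went from 0.166% to 6.14%, and in miR-277-3p nucleotide 17 went from 0.0212% to 5.02%. Other positions were high before labelling: nucleotide 22 of miR-998-3p stood at 25.97% at 0 h and 29.6% at 24 h, nucleotide 24 of miR-996-3p at 8.77% and 8.38%, and nucleotide 23 of miR-184-3p at 7.75% and 14.6%.

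Over all labelled times the ratio was lower in the arms that were higher after oxidation (log2 −3.01 over 25 arms, against −1.21 over 33). Across 64 arms, the 24 h oxidised over unoxidised T>C ratio was not correlated with the change in abundance after oxidation past a threshold of 0.05 (Pearson r = −0.190, p = 0.130; Spearman rho = −0.246, p = 0.0506). In miR-34-5p at 1 h, 5.09% of the 24 nt reads and 0.458% of the 21 nt reads carried T>C in the unoxidised library, and at 24 h 18.3% and 8.72%.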
